A study of Arabidopsis thaliana with 12 samples.

How the data were processed

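The series holds 12 one-channel array profiles of total RNA from *Arabidopsis thaliana* Columbia 0 plants, 6 control samples grown at 80 µE and 6 recovery samples taken after 1 h at 1000 µE and a return to 80 µE. Group and replicate number were read from the sample titles. The labels give 2 h of recovery in the titles and descriptions and 1 h in the source names, and this was not resolved. One comparison, recovery against control, followed from the labels.

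The deposited values are intensities on a linear scale from 0 to a ceiling of 100, with no negative values. The array type, scanner, background correction and normalisation behind these intensities are not given in the sources used here, so whether and how the authors scaled the columns stays unknown. The column medians ran from 0.196 to 0.458 and the column means from 0.836 to 0.990. By sample, the medians of control 1 to 6 were 0.284, 0.271, 0.217, 0.212, 0.200 and 0.202, and those of recovery 1 to 6 were 0.458, 0.448, 0.197, 0.196, 0.426 and 0.428. Between 4.97% and 11.1% of probes per sample were listed at 0, and up to 7 probes per sample stood at the ceiling, where differences are compressed. No background or spot-level readings were analysed here, so the number of arrays and the floor set the precision.

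Because the columns did not agree within 1%, which was the condition fixed before the data were examined, the linear values were quantile-normalised (limma 3.58.1, R 4.3.3), values under the 5th percentile of the positive normalised values, 0.0298, were set to it, and log2 was taken. The floor was -5.07 on the log2 scale, so a fold change of a gene near it is understated. Of 3439 probes, 692 were assigned to 1 gene by the platform annotation, 870 to several and 1877 were unnamed here. Of the 692, 690 were found by gene number in the reference gene table (assembly TAIR10.1), from which current symbols and loci were taken. The series names no genome build, so no positions are given. Probes with several genes or without a name entered the fits as single features and were not named. The 1 gene with 2 probes, AT2G25870, was averaged on the log2 scale, although its probes disagreed, with log2 fold changes of -0.28 and 0.51. This left 3438 features.

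Groups were compared with limma (lmFit and eBayes, no trend, not robust) over all 12 samples with no covariate, with two-sided p-values and Benjamini-Hochberg adjustment over the 3438 features, and features past an adjusted p under 0.05 were called. Every adjusted p given for a gene comes from this limma fit unless another setting is named. Gene lists with at least 5 measured genes were tested with limma camera at a preset correlation of 0.01, with fry and camera with an estimated correlation beside it. With 1 of the 24 fixed lists large enough, the adjusted p of that list equals its p. The 24 lists, 429 loci in all, were written from memory of plastid and stress pathways before the data were examined. A further 8 lists of 74 loci were put together from the gene names on the array after the data had been opened and before any test was run on them, and they are reported apart from the others. The text names up to 12 rises and 12 falls by size among called genes with their own probe and every recovery value on the same side of the control mean, up to 4 members with the smallest p per list, and 6 genes listed by name, with 2 IDs at most per direction for probes without a name.

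Whether replicate numbers pair the samples was checked before fits were compared. The number is the one that ends each sample title. Deviations from the group mean, across features, correlated at 0.110 to 0.462 between samples of the same number in the 2 groups and at -0.229 to 0.008 between samples of other pairs, and each of the 12 samples was closest to its own number across groups. With the other sample of the same pair in the other group they correlated at 0.081 to 0.168. For samples 3 and 4 the same-number values were 0.110 and 0.111 and the other values 0.088 and 0.081, so pairing by single number is not established there. All 6 same-number correlations were over 0.1, and the numbers were taken to pair the samples. The fit with the replicate number as a block (106 features called) is given wherever it changes a call. That fit has no term for likeness between samples of a pair within a group, so a call kept in it may still be false. Within a group, samples 1 and 2, 3 and 4, and 5 and 6 correlated at 0.853 to 0.942 on the log2 scale and samples of different pairs at 0.683 to 0.824. No label calls these technical repeats, so all 12 samples stayed in the main fit, and fits with the pairs averaged or as a random block (duplicateCorrelation, correlation 0.663) were run as alternatives. With 3 pairs against 3, an exact two-sided permutation test of a single gene cannot go below 0.1.

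The fits were tested on simulated data of 3438 features with 100 features changed by 1 and 100 by 2 on the log2 scale. With independent samples the 12-sample limma fit recovered 18% of the smaller and 67% of the larger changes, and 9 of 94 calls were false. With noise shared within the pairs of a group, at the correlation of 0.663 found in these samples, it recovered 37% and 82%, but 90 of 209 calls were false (43.1%). The fit with a replicate block gave 82 false calls of 189 there, the fit with pairs as a random block 5 of 61, and the fit on averaged pairs made 0 calls. Noise shared by control and recovery samples of the same number, which these samples also show, was not simulated. The rates of false calls may therefore differ in these samples. The set test, run on simulated independent samples only, gave a changed list an adjusted p of 0.000489 and called 0 of 20 unchanged lists. Its false calls with noise shared within pairs were not simulated.

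Alternatives fixed before the data were examined were the values as deposited, median centring, cyclic loess, a filter leaving out the dimmest 25% of features, a pseudocount in place of the floor, the replicate block, averaged pairs, pairs as a random block, eBayes with trend and robust, array weights, each of the 12 samples left out, probes tested one by one, an adjusted p under 0.01, and the set tests named above. Settings without samples 3 and 4 and a pair of fits with the pairs as a fixed block were added after the data were seen. Without samples 3 and 4 of both groups, each group keeps samples 1 and 2 and samples 5 and 6. That fit has no term for these pairs, like the 12-sample fit with 43.1% false calls in simulation. Its adjusted p-values may therefore be too small. Figures were drawn with matplotlib 3.10.9.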

Results

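The series measured RNA levels in wild-type *Arabidopsis thaliana* plants of the Columbia 0 ecotype on an array of 3439 probes. Total RNA of 12 samples was read, 6 from plants grown at 80 µE, the control group, and 6 from plants moved to 1000 µE for 1 h and then returned to 80 µE, the recovery group. The labels disagree on the time back at 80 µE, which is 2 h in the titles and descriptions and 1 h in the source names. The question was how transcript levels during recovery from a light stress compared with those of plants that had not left the growth light. The titles give 0 h for the control and 2 h for the recovery samples. Sampling time, and so time of day, may therefore differ between the groups. Its effect cannot be told apart from that of light. Each sample gave a value for every probe, and 171 to 383 probes per sample were listed at 0. The samples of a group resembled each other in the pairs 1 and 2, 3 and 4, and 5 and 6, and the labels do not say which samples came from separate plants, so p-values measure the spread between these samples, which may in part be technical.

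After high light and recovery, the transcript of NADP-malate dehydrogenase (AT5G58330), the chloroplast enzyme that exports reducing power as malate, was 4.94-fold higher than in control plants. CCL (AT3G26740), a transcript known for its clock-controlled level, was 3.71-fold higher. For CCL, as for every gene here, an effect of sampling time cannot be told apart from that of light. The largest fall among named genes was that of AT2G36480, 8.18-fold higher in control than in recovery plants over all 12 samples. That difference was smaller in samples 3 and 4. AT-HF (AT4G26900), the imidazole glycerol phosphate synthase of histidine synthesis, was 3.82-fold higher in control plants over all 12 samples. Its log2 difference was -0.10 in samples 3 and 4, and its limma call was lost with the replicate number as a block (adjusted p = 0.0870). In all, 104 of 3438 features passed an adjusted p under 0.05 with limma, 41 higher and 63 lower in recovery plants, and 21 of them were genes with a probe of their own, 11 higher and 10 lower. With the pairs of samples as a random block, limma called 3 features, of which CCL was the 1 named gene.

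Among the genes that rose, NADP-malate dehydrogenase (AT5G58330) went from a log2 intensity of -0.99 ± 0.37 (SD, n = 6) in control to 1.32 ± 0.70 (SD, n = 6) in recovery samples, a log2 fold change of 2.31 with a standard error of 0.32 and an adjusted p of 0.00413. CCL went from 1.32 ± 0.40 to 3.21 ± 0.32 (SD, n = 6 per group), a log2 fold change of 1.89 with a standard error of 0.23 and an adjusted p of 0.0030. A pair of pentatricopeptide repeat genes, whose products bind organelle RNA, rose together. AT3G13150 had a log2 fold change of 1.56 with a standard error of 0.25 (adjusted p = 0.00776), and AT3G26630 one of 1.45 with a standard error of 0.32 (adjusted p = 0.0350). With the replicate number as a block, AT3G26630 had an adjusted p of 0.0500213 and was no longer called. AT5G52810, which codes for a reductase of pipecolic acid synthesis in plant immunity, rose by 1.38 on the log2 scale. The other genes that rose and met the rule for naming were AT1G35510 (1.35), AT4G39760 (1.26), AT1G67800 (1.23), the chromatin remodeller gene chr31 (AT1G05490, 0.99) and AT1G12100 (0.78), the last with an adjusted p of 0.0510 under the replicate block. All 10 of these genes were higher in recovery than in control for each of the 6 replicate numbers, which their choice from these same samples favours.

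Among the genes that fell, AT2G36480 went from 1.37 ± 0.85 in control to -1.67 ± 0.90 in recovery samples (SD, n = 6 per group), a log2 fold change of -3.03 with a standard error of 0.48 and an adjusted p of 0.00776. Its difference was -3.95 in samples 1 and 2, -0.90 in samples 3 and 4 and -4.24 in samples 5 and 6, so the fold depends on the pair. AT-HF had a log2 fold change of -1.93 with a standard error of 0.46 (adjusted p = 0.0433), and its difference was -0.10 in samples 3 and 4. AT5G10920, which codes for the argininosuccinate lyase of arginine synthesis, fell by 1.21 on the log2 scale. AT2G46630 had a log2 fold change of -1.74 with a standard error of 0.21 (adjusted p = 0.0030), and AT3G56290 one of -1.83 with a standard error of 0.24 (adjusted p = 0.00302). AT1G02020 fell by 1.78, iqd32 (AT1G19870), a gene of the calmodulin-binding IQ-domain family, by 1.52, and AT3G09050 by 1.00. CUTA (AT2G33740), a copper-binding protein of the chloroplast, fell by 0.65 and AT1G62250 by 0.60. With the replicate number as a block, the adjusted p of AT-HF was 0.0870, that of AT1G02020 0.0732, that of AT1G62250 0.0667, that of CUTA 0.0595 and that of iqd32 0.0537, so these 5 calls were lost. With the pairs of samples as a random block or averaged, no gene that fell was called. Under the random block the adjusted p was 0.0501 for AT3G56290, 0.0549 for AT2G36480 and 0.0865 for AT2G46630.

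**Figure D1:**
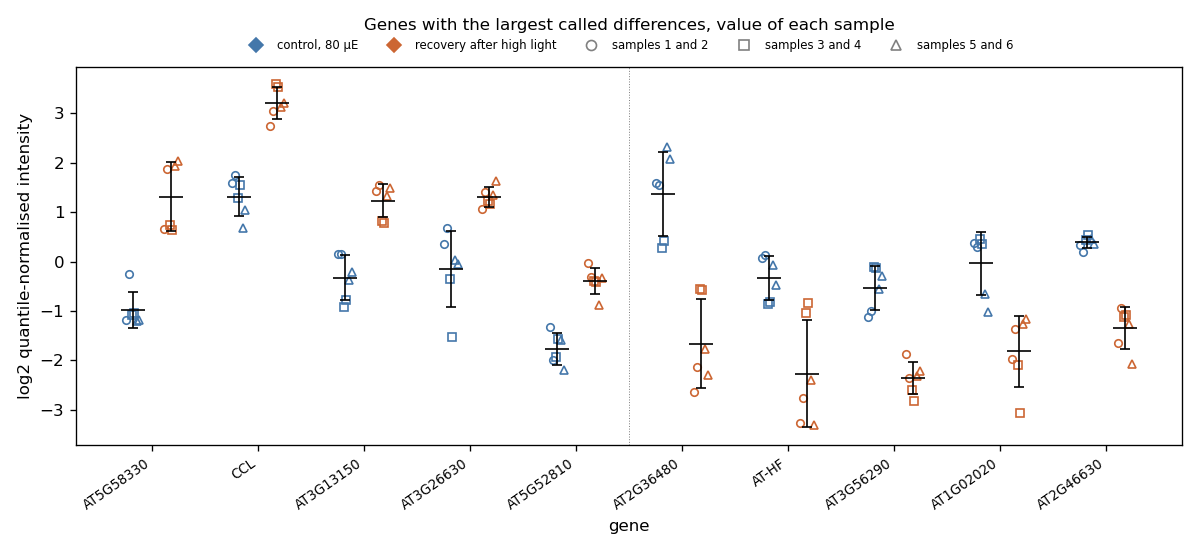
Log2 quantile-normalised intensity (y axis) in each of the 12 samples for the 5 genes with the largest rise and the 5 with the largest fall among those called (x axis), in control (blue) and recovery (orange) samples, with the group mean and SD as bars and a marker shape for each pair of sample numbers. The 6 recovery values of CCL all lie above the 6 control values, with means of 3.21 and 1.32, and for AT-HF the recovery samples 3 and 4 lie nearest the control samples.

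The remaining called features had no single gene name, 17 being probes assigned to several genes and 66 probes unnamed here. The 41 higher features had a median log2 fold change of 1.36 and a range of 0.69 to 2.88, and the 63 lower ones a median of -1.09 and a range of -3.06 to -0.60. All 104, chosen over these same samples, went in the same direction in each of the 3 pairs of samples. Probe 4341 showed the lowest log2 fold change of all called features, -3.06 with a standard error of 0.35. AT5G38360, a called gene singled out after its values were seen, had a log2 fold change of 1.56 (adjusted p = 0.0466), but 4 of its 6 control values were at the floor, so its size is not interpretable. Its call was lost with the replicate number as a block (adjusted p = 0.0898).

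Of the gene lists fixed before the data were examined, 19 members in 9 of 24 lists had a probe of their own, and none of these 19 genes passed the limma test over all genes (2 had an unadjusted p under 0.05). The plastid ribosomal proteins, 6 of which were measured, were lower as a group in recovery plants (limma camera, adjusted p = 0.0295), with a median log2 fold change of -0.57. The call was lost with an estimated correlation (adjusted p = 0.0591), and without samples 3 and 4 (adjusted p = 0.0713). It was also lost with the pairs of samples as a random block (adjusted p = 0.0566). The members of the list all had log2 fold changes below 0 under quantile normalisation, median centring, cyclic loess and the pseudocount, and 4 of 6 did on the deposited scale, where the median of all features was itself shifted to 0.43. Without samples 3 and 4 of both groups 5 of 6 did, RPL5 (AT4G01310) having 0.16. The large-subunit protein gene RPL17 (AT3G54210) had a log2 fold change of -1.16 with a standard error of 0.35 (adjusted p = 0.109), and it alone passed when adjusted over the list alone (adjusted p = 0.0394). RPL17 was called over all genes without samples 3 and 4 (adjusted p = 0.0307), in a fit with no term for the pairs. RPS10 (AT3G13120) had one of -0.59, which was -0.08 without recovery 2, and RPL34 (AT1G29070) one of -0.54. RPL29 (AT5G65220) had one of -0.87, but 5 of its 6 recovery values were at the floor, so its size is not interpretable.

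Photosynthesis genes with a probe of their own did not pass the test. In the Calvin-Benson cycle, 0 of 2 measured genes passed over all genes and 1 when adjusted over the list alone, the phosphoribulokinase gene PRK (AT1G32060), with a log2 fold change of -0.67 and a standard error of 0.20 (adjusted p = 0.0963 over all genes, 0.0105 over the list). SBPASE (AT3G55800) had a log2 fold change of 0.06 with a standard error of 0.78. Of 3 photosystem II subunits, none passed over all genes or when adjusted over the list alone, with values of 0.35 for PSBW, -0.44 for PSBY and -1.17 for PSB27, and PSB27 had an adjusted p of 0.0492 under the replicate block, 0.654 with the pairs as a fixed and a random block and 0.802 with averaged pairs. The antenna gene LHB1B2 (AT2G34420) had a log2 fold change of 0.23 with a standard error of 0.17, and the photosystem I gene PSAN one of 0.03 with a standard error of 0.26. The lists of chlorophyll and haem synthesis (CHLM, 0.65, and AT1G74470, 0.03), antioxidant enzymes (AT3G52960, 0.34), plastid proteases (SPPA, -0.56) and fatty acid synthesis (FATB, 0.03, and AT1G24360, -0.28) also had 0 members past the test over all genes or when adjusted over the list alone. ELIP1, ELIP2, APX2, FER1, LHCB2.3 and PSBS, which the rule for named genes also listed, had no probe of their own and were not analysed here.

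The number of calls depended on how the pairs of samples entered the fit. With the pairs as a fixed block and each group's pair as a random block, a fit chosen after the data were seen, 92 features passed, and 60 of them were among the 104. With each pair averaged, 3 against 3, limma called 0 features (203 at an unadjusted p under 0.05), as it did in simulated data with changed features and noise shared within pairs. With the pair as a random block it called 3, of which CCL was the 1 named gene (adjusted p = 0.0473). Leaving out samples 3 and 4 of both groups gave 362 calls, 78 of them among the 104, in a fit with no term for the pairs that remain. On the values as deposited, where the median of all features was shifted by 0.43, 79 features were higher and 30 lower, and after median centring 14 were higher and 51 lower, against 41 and 63 under quantile normalisation. With the replicate number as a block, 106 features passed, and 58 of them were among the 104.

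**Figure D2:**
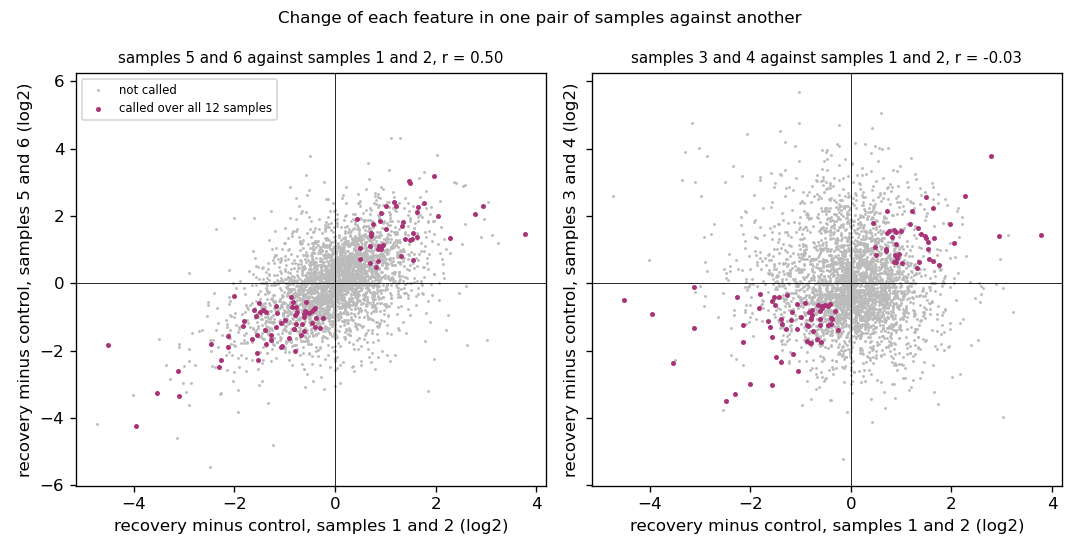
Difference between recovery and control (log2) of each of 3438 features in samples 5 and 6 (left, y axis) and in samples 3 and 4 (right, y axis) against that in samples 1 and 2 (x axis), each a mean over the 2 samples of a pair, with called features in purple. Across features, which are not independent replicates, the correlation is 0.50 on the left and -0.03 on the right.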

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

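The splits of the 12 samples and the comparison of differences within pairs were set out before their results were seen; the splits of whole pairs, the correlation within pairs and the tests on samples 3 and 4 were chosen after related values had been seen. Each group of 6 samples was searched for a sample far from the rest, by the gap to its nearest neighbour as a share of the group's range. Of 130 such groups 9 were past Dixon's critical value at 95%, where chance gives about 1 in 20 for independent normal values. Samples of a pair resemble each other and some values are tied at the floor, so that rate may not hold here.

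Among called genes, control 2 stood above the other controls for AT5G58330 (log2 -0.25 against -1.20 to -1.04, gap share 0.826), control 3 below them for AT1G12100 (0.642) and recovery 5 below the other recovery samples for AT5G10920 (0.673). Among genes that were not called, control 6 stood low for SBPASE (0.811), AT2G37420 (0.673) and CHLM (0.665). Recovery 1 stood low for AT5G55580 (0.810) and recovery 2 for AT3G13120 (0.643). For AT5G65220 the gap share was 1 because 5 of 6 recovery values were at the floor.

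The 104 calls between recovery and control, CCL and AT2G36480 among them, were set against other splits of the samples. Of 100 splits drawn at random, 2 gave as many calls, the real one included. The highest other gave 111 and the median of the others was 0. The drawn splits that kept all pairs whole gave 50, 81 and 111 calls beside the real one, and those that broke a pair gave at most 4. The count thus depends on keeping the pairs whole. Since samples of a pair resemble each other, the 100 splits cannot exclude chance. Most of those splits break the pairs; with the pairs kept whole, 3 of the 10 splits gave as many calls, the highest other gave 196, and 10 splits are too few for a share under 0.05. Of the 32 splits that part every replicate number, 2 gave as many calls with the replicate block (106 for the real one, 129 for the split in which samples 3 and 4 change groups). Of these 32, 4 keep the pairs whole, and the other 2 of these gave 0 calls. Pairs alone thus did not bring calls in every split, and the light treatment and the time of sampling stay open as sources of them. For the plastid ribosomal list, 8 of 100 splits gave a camera p as small as the real 0.0295, the smallest other being 0.00673, so chance is not excluded.

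Samples of a group resembled each other in the pairs 1 and 2, 3 and 4, and 5 and 6. The median correlation of their deviations from the group mean was 0.440 within pairs and the highest between pairs was -0.152, which is consistent with 2 readings of 1 hybridisation or 1 RNA. The difference between the 2 samples of a pair correlated across groups at 0.0626 to 0.518 for the same numbers and at 0.021 to 0.049 for other numbers, so a physical array or spotting run shared by control and recovery samples of a number is not settled. No biological explanation was tested for the pairs, since the labels name no plants, pools or days. If the pairs are repeat readings, all 104 calls, those of CCL, AT5G58330 and AT2G36480 included, rest on 3 samples per group. With averaged pairs limma called 0 features.

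In samples 3 and 4 the difference between recovery and control did not correlate across features with that in the other pairs (-0.03 and -0.01, against 0.50 between those), as in AT-HF (-0.10 there, -3.11 and -2.59 in the others), although the 104 called features, chosen over all 12 samples, went the same way there. On an axis from control (0) to recovery (1) of the other samples, control 3 and 4 lay at 0.0611 and recovery 3 and 4 at 0.010 (0.284 and 0.294 in the 860 brightest features). The position of control 3 and 4 argues against control and recovery labels exchanged between them. An exchange alone would make the correlations with the other pairs clearly negative. At -0.03 and -0.01 they argue against it as the sole source. The split that exchanges them gave more calls with the replicate block, 129 against 106. That fit gave 82 false calls of 189 in simulation with noise shared within pairs, so these counts do not decide it. An exchange together with another difference of that pair is not excluded. On the deposited scale a trend with brightness took up 17.56% and 14.04% of the variance of the differences in the other pairs and their correlation was 0.490 without it and 0.540 with it, which argues against that trend as its whole source, while another bias that runs with the higher medians of recovery 1, 2, 5 and 6 (0.426 to 0.458, against 0.197 and 0.196) stays open. Of 54 features past an adjusted p under 0.01 in the other 8 samples, 48.1% went the same way in samples 3 and 4, against 50.7% of all features. In these 54, recovery 3 and 4 lay nearer the control mean than the recovery mean of the other 8 samples in 68.5%, and control 3 and 4 did so in 64.8%. RNA of unstressed plants in the libraries labelled recovery 3 and 4 stays open. These libraries lay closer to the other controls (correlations of 0.778 to 0.842) than to the other recovery samples (0.754 to 0.774). The placement in the 54 features does not set these libraries apart from control 3 and 4. Control 3 and 4 stood apart too (correlations of 0.683 to 0.746 with the other controls, against 0.802 to 0.807 between those), so odd controls stay open as part of the lost correlation, as do, untested, plants of that pair that answered the light differently or had already returned to the control state, as no label sets that pair apart.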

How the results depend on the processing

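The settings without samples 3 and 4 and those with the pairs as a fixed block were chosen after the data were seen. The count of 104 called features stayed within 1.5 times under the deposited scale (109), the dim filter (90), the pseudocount (73), trend and robust (108), the replicate block (106), single probes (104), control without samples 3 and 4 (108) and pairs as a fixed with a random block (92). It was 65 after median centring, 60 with cyclic loess, 296 with array weights, 21 at an adjusted p under 0.01, 3 with pairs as a random block, 0 with averaged pairs (203 at an unadjusted p under 0.05) and 0 with averaged pairs and a pair block (314). It was 362 without samples 3 and 4 of both groups and 257 without those of recovery; the cause was not tested. Leaving out 1 sample gave 42 to 91 calls, the counts under 70 being 42 without recovery 5, 46 without recovery 6, 51 without recovery 2, 54 without recovery 1, 55 without control 3 and 66 without control 4. The number of fixed lists called, 1, was 0 on the deposited scale, after median centring, with pairs as a random block, with an estimated correlation, at an adjusted p under 0.01, without samples 3 and 4 of both groups and without those of control. With 1 sample left out it was 0 to 1, the loss coming without control 3 (adjusted p = 0.0653). Over all settings its adjusted p ran from 0.0068 to 0.130, and with the dim filter under 5 of its genes were left, so no value exists. The median log2 fold change, -0.02, was 0.43 on the deposited scale and -0.13 after median centring.

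No called named gene changed sign in any setting, which the choice of these genes from the same samples favours. Of these 20 genes, 9 were called whichever sample was left out, 13 in the replicate block, 17 without samples 3 and 4, 1 with pairs as a random block and 0 with averaged pairs. The replicate block called PSB27 (not called with the pairs as a random block, adjusted p = 0.924, or as a fixed with a random block, 0.654) and the pentatricopeptide repeat list in addition, lost 7 calls of these 20 genes and that of AT5G38360, and changed no other call of a named gene or list. Of 42 named genes that were not called, 7 were called without samples 3 and 4 of both groups, 4 without those of recovery, 3 with array weights, 2 on the deposited scale and 1 each after median centring, in the replicate block, without control 1 and without recovery 4. Sign changes occurred in 15 named genes that were not called. On the deposited scale, against its shift of 0.43, PSAN had -0.0730, Z-ISO 0.35, AT1G61990 0.29, AT1G24360 0.26, AT2G46910 0.00476, AT1G29070 0.23 and SPPA 0.0560. After median centring PSBW had -0.29, LHB1B2 -0.53, SBPASE -0.25, AT1G74470 -0.40 and PSAN -0.63. With cyclic loess SBPASE had -0.0732 and PSAN -0.0724, and with the pseudocount SBPASE had -0.00094. With array weights PSBW had -0.0235, AT3G52960 -0.48, SBPASE -0.43, AT1G74470 -0.39, PSAN -0.24 and AT2G46910 0.46. Without samples 3 and 4 of both groups PSBW had -0.0765, AT3G52960 -0.42, FATB -0.29, AT1G74470 -0.49, PSAN -0.47 and Z-ISO 0.29. Without those of recovery AT3G52960 had -0.27, FATB -0.33, AT1G74470 -0.16, PSAN -0.26, Z-ISO 0.25 and AT1G61990 0.30. Without those of control PSBW had -0.11, AT1G74470 -0.33, PSAN -0.20, AT1G24360 0.18 and PSBY 0.0583. With 1 sample left out the ranges were -0.00988 to 0.38 for AT3G46950, -0.61 to 0.46 for SBPASE, -0.11 to 0.20 for FATB, -0.15 to 0.12 for AT1G74470, -0.12 to 0.12 for PSAN, -0.34 to 0.0789 for Z-ISO, -0.42 to 0.15 for AT1G61990 and -0.61 to 0.16 for AT1G24360. The cause of these was not tested. Signal over background was not analysed here, and values at the floor have no order.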

Other observations

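The lists described here were put together from the gene names on the array. This was done after the data had been opened and before any test was run on them. The settings without samples 3 and 4 were chosen after the data were seen. With these left out of both groups, the fit has no term for the remaining pairs, so its calls given below may hold an excess of false ones. None of the 8 lists passed limma camera, with adjusted p from 0.147 to 0.847. Among 17 pentatricopeptide repeat genes, AT3G13150 and AT3G26630 rose, 15 did not pass the test, and 12 had a log2 fold change above 0, with a median of 0.42 (11 to 15 genes under the other scalings, with a median of 0.11 after median centring and 0.66 on the deposited scale). That list had an adjusted p of 0.147, of 0.868 with an estimated correlation and of 0.0403 with the replicate block, which changes the call, but of 0.0748 with the pairs as a random block and 0.492 without samples 3 and 4. Its gene CRR21, needed for editing of a plastid transcript, had a log2 fold change of 1.06 with a standard error of 0.32 (adjusted p = 0.109), and AT4G14050 one of -0.90 (adjusted p = 0.125).

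Among 8 genes of redox regulation and antioxidant defence, NADP-malate dehydrogenase (AT5G58330) rose and 7 did not pass. CCS (AT1G12520), the copper chaperone of superoxide dismutase, had a log2 fold change of -1.72 with a standard error of 0.45 (adjusted p = 0.0612), and 3 of its recovery values were at the floor. It was called without recovery 4 (adjusted p = 0.0128), with array weights (adjusted p = 0.00476), and without samples 3 and 4 of both groups (adjusted p = 0.00418) or of recovery alone (adjusted p = 0.00268), but with recovery values at the floor the size of its change is not interpretable. GLDH, the last enzyme of ascorbate synthesis, had one of -0.66 (adjusted p = 0.110) and GLX2-1 one of 0.77 (adjusted p = 0.321), and without samples 3 and 4 GLX2-1 was called (1.44, adjusted p = 0.0230). Among 9 genes of amino acid and nucleotide synthesis AT-HF fell and 8 did not pass, with values of -1.19 for CBL, -0.89 for APS4 and 1.32 for AT2G35390, which was called without samples 3 and 4 (0.76, adjusted p = 0.0400).

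Genes of dividing cells included 8 histone H3 and kinesin genes, none of which passed limma's test (2 had an unadjusted p under 0.05). The histone H3 genes AT1G13370 and AT1G09200 had log2 fold changes of -1.16 (adjusted p = 0.218) and -1.14 (adjusted p = 0.281), and of -1.65 (adjusted p = 0.0102) and -1.62 (adjusted p = 0.0187) without samples 3 and 4, while the kinesin genes AT4G14330 and AT2G37420 had 1.28 and 1.18 over all 12 samples, and 0.64 (adjusted p = 0.195) and 1.58 (adjusted p = 0.164) without samples 3 and 4. Of 16 photosystem, antenna and NDH complex genes, 5 tetrapyrrole and carotenoid genes, 6 mTERF genes and 5 fibrillins, 0 passed limma's test over all 12 samples, and 0 had an unadjusted p under 0.05. PYG7 (AT1G22700), singled out after its values were seen, had a log2 fold change of 0.37 over all 12 samples (adjusted p = 0.846) and was called at -0.98 without samples 3 and 4 (adjusted p = 0.0499881). LPA19, an assembly factor of photosystem II, had a log2 fold change of -0.56 (adjusted p = 0.328), and AT1G74730 one of 1.11 (adjusted p = 0.313). The plastid glutamyl-tRNA reductase gene HEMA3 had one of -0.34, the mTERF gene AT1G62150 one of 0.36 (0.88 and called without samples 3 and 4, adjusted p = 0.0326) and the fibrillin gene AT5G09820 one of 0.44.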
